A study of Mus musculus with 4 samples.

How the data were processed

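The series holds 4 droplet-based single-cell RNA libraries of CD45+ immune cells from mouse ear skin, 2 from Card14 E138A/+ mice and 2 from wild-type (WT) littermates. E138A is a coding change in Card14, which encodes a scaffold protein that drives NF-kB signalling and is expressed mainly in keratinocytes. The deposited matrix holds raw UMI counts per gene and cell, as whole numbers with no normalization. Cell Ranger 2.1.1, Seurat 4.0 and the mm10 (GRCm38) build are named per the submitters' processing notes, with no role given. Barcodes carry a library name, which was matched to genotype and replicate by the labels. The 2 libraries of a genotype come from separate samples. In each genotype 1 library holds Xist UMIs and 0 UMIs of 4 Y-linked genes and the other the reverse, so the 2 share no animal, but the labels do not say whether each is 1 animal or a pool. A p-value measures the spread between these samples. The labels also give each library its own batch name, so batch cannot be separated from library.

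Each library's filters before deposit were not stated. Deposited cells had at least 501 detected genes. Cells with at least 200 genes and at most 15% mitochondrial UMIs were kept, which left 7809 of 7972 cells. No doublets were removed. A simulated-doublet score was computed, and the 5% of cells per library with the highest score were left out in an alternative. Counts were log-normalized to 10000 UMIs per cell, and 2000 variable genes ranked within libraries were used for 30 principal components, 20 nearest neighbours and Leiden clusters at resolution 1, without integration. Il17a, Il17f, Il22, V, D and J segments of T cell receptor and immunoglobulin genes, and mitochondrial, ribosomal, sex-linked, cell cycle, dissociation-stress and interferon response genes were left out of the variable genes. The 24 clusters were named with 26 marker sets. A name needed at least 3 markers, and at least 50% of the set, raised by at least 1 on the log2 scale and detected in at least 20% of cells. The mean log2 fold of the set had to reach 1. Other sets, T cell sets aside, had to hold fewer of the 50 leading genes. Clusters with the same name were joined, which gave 23 classes. A cluster kept its number where it met no set or where another set held more of its 10 leading genes. A class name therefore means cells that resemble that type by the fixed markers.

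UMIs were summed per library, or per library and class for classes with at least 20 cells in each library. The sums were compared between genotypes with the edgeR quasi-likelihood F test with TMM scaling and filterByExpr. Adjusted p-values are Benjamini-Hochberg values over the genes tested, with a threshold of 0.05. Standard errors (SE) of log2 folds were derived from the fold and its F statistic. Class shares were compared with the same test on numbers of cells per library, adjusted over the 23 classes. Shares of T cells with a cytokine UMI were tested in the same way, with the spread taken over the classes, after thinning each cell to 1500 UMIs and without thinning. The plan named no adjustment for these shares. An adjustment over the 7 cytokine sets at each depth was added after their unadjusted p-values had been seen, and the closing section gives the calls without it. An exact permutation test of 2 libraries against 2 cannot reach 0.05, since the smallest p it allows is 1 in 3. For 28 gene lists, camera of limma with a preset correlation of 0.01 was adjusted over the lists measured with at least 5 genes. Camera with an estimated correlation and fry were run beside it. Levels are in CPM, UMI counts scaled to the total of their library or class. A fold against a genotype with no UMIs is a lower bound, set against 3 UMIs over that genotype, and 1 to 3 UMIs give a ratio with its 95% counting interval. Intervals of shares are exact (Clopper-Pearson) at 95%. Intervals and floors cover counting error only.

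The genes named are Card14 and fixed cytokines, the 10 largest and 10 smallest log2 folds among genes past the threshold with both E138A libraries on 1 side of both WT libraries, and up to 4 members of each list in the class where that list's p is smallest. Where fewer than 4 genes passed in a direction, the 4 with the smallest p were added as values. Unnamed gene models, receptor segments, ribosomal protein genes and sex-linked genes were not named. Lists, marker sets, tests and this rule were fixed before the data were examined. The sum of all T cells, the separate tests of Il17f, Il22, Il13 and Ifng, the adjustment over cytokine sets, the crossed pairing of samples, the separate fits of the 2 macrophage clusters, the all-cell fit without the top doublet scores and the tests of the gamma-delta class and of cluster 13 in the closing section, except that of its doublet score, were added afterwards.

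The tests were tested on simulated data of the same size. In the sum of all cells, 74.7% of genes changed 4-fold and 23.7% of those changed 2-fold were recovered, with 4 false calls among 12316 genes. The share test recovered 92.0% of classes changed 8-fold and called 1.80% of unchanged classes, at a fixed dispersion of 0.15 that was not estimated from these data. A wider spread, as that of ILC2 between the WT libraries (14.6% and 1.90%), was not simulated. Alternatives covered the test tool, the scaling, the filters on genes and cells, the doublet score, the cluster resolution, centring of components per library, thinning to equal depth, a term for replicate number, and leaving out each library. Positions are those of GENCODE vM21 on GRCm38, which holds 98.7% of the symbols. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, igraph 0.11.9, leidenalg 0.10.2 and matplotlib 3.10.9. R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Sequencing reads were not used here.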

Results

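RNA was counted in single CD45+ immune cells sorted from the ear skin of Card14 E138A/+ mice (E138A) and their wild-type littermates (WT). The series title names skin Th17 cells, T cells that make IL-17, so the comparison asks which immune cells and genes differ between the genotypes. Each genotype has 2 libraries, named WT 1, WT 2, E138A 1 and E138A 2, and every test below compares 2 libraries with 2. Kept cells numbered 683 in WT 1, 1527 in WT 2, 3147 in E138A 1 and 2452 in E138A 2. Their totals were 3190959, 10197262, 16250747 and 11672650 UMIs. Median UMIs per cell, over all deposited cells of each library, were 3859, 5511, 4086.5 and 3575. Ptprc, which encodes CD45, was at 310, 328, 300.05 and 286.9 CPM. Card14 (chromosome 11, 119307768 to 119345375, overlapped by Sgsh on the other strand) had 2, 0, 1 and 1 UMIs, below the 3-UMI floor in each library. The genotype labels could not be checked from these counts, and no fold of Card14 was computed. Xist UMIs were found in WT 1 and E138A 1 and Ddx3y UMIs in WT 2 and E138A 2, so each such pair holds 1 library of each genotype and allows no test within it.

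The mix of immune cells differed between the genotypes. Dermal gamma-delta T cells, the innate-like T cells of WT skin that make IL-17, fell from 13.8% of cells in WT 1 and 11.5% in WT 2 to 0.159% in E138A 1 and 0.367% in E138A 2. This was a log2 fold of -5.57 (SE 0.69, adjusted p = 0.00502). Group 2 innate lymphoid cells (ILC2), tissue lymphocytes that make type 2 cytokines, fell from 14.6% and 1.90% to 0.127% and 0.245% (log2 fold -5.43, SE 1.29, adjusted p = 0.0295). Langerhans cells, the antigen-presenting cells of the epidermis, rose from 0.732% and 0.196% to 8.07% and 5.83% (log2 fold 4.04, SE 0.79, adjusted p = 0.0167). Cluster 13, T cells by the marker sets, rose from 0.439% and 0.393% to 2.73% and 4.20% (log2 fold 3.05, SE 0.58, edgeR adjusted p = 0.0167). It kept its number because another set held more of its 10 leading genes, and its leading genes include Il22, Il17f and Il17a. Type 2 conventional dendritic cells (cDC2) fell from 10.4% and 10.2% to 2.38% and 1.79% (log2 fold -2.30, SE 0.49, adjusted p = 0.0168).

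Of the 23 classes, 8 passed in edgeR, 4 higher and 4 lower. Clusters 1, 4 and 12 are the other 3, and their sizes are not compared because many of their 30 leading genes also differed between genotypes within other classes (17 higher and 3 lower for cluster 1, 1 and 16 for cluster 4, and 13 and 2 for cluster 12). Of the 30 leading genes of cDC2, 3 were higher and 4 lower in E138A within another class, and cluster 1, with 15 WT and 1005 E138A cells, shares cDC2-type genes such as Mgl2. For Langerhans cells, with 8 WT and 397 E138A cells, 5 of the 30 were higher and 1 lower within another class. Macrophages were at 10.8% and 22.1% in WT and 17% and 20.2% in E138A (log2 fold 0.17, adjusted p = 0.802). Monocytes had a log2 fold of 1.13 (adjusted p = 0.187; 0.42 without E138A 1, 0.11 at resolution 2 and 0.16 with centred components), neutrophils of 1.99 (adjusted p = 0.144; 3.67 without WT 2 and 1.29 without E138A 1; without the top doublet scores they passed, at 3.65 and 0.0166), regulatory T cells of 1.15 (adjusted p = 0.187) and CD4 T cells of -0.64 (adjusted p = 0.379), none of which passed with all cells kept. Without E138A 1, 0 classes passed in edgeR, with 6 at an unadjusted p under 0.05, against 4 without WT 2 and 3 without E138A 2. The gamma-delta class missed the threshold only without E138A 1 (adjusted p = 0.0712; its log2 fold was -6.25 without E138A 2), and ILC2 without E138A 1 (0.259) or E138A 2 (0.194), its log2 fold being -3.34 without WT 1 and -6.28 without WT 2. Langerhans cells missed it without WT 2 (0.0715), E138A 1 (0.141) or E138A 2 (0.117), their log2 fold being 5.11 without WT 1 and 3.24 without WT 2. Cluster 13 and cDC2 missed it without any 1 library, at 0.0515 and 0.0547 without WT 1, 0.0755 and 0.0715 without WT 2, 0.0809 and 0.141 without E138A 1, and 0.117 and 0.192 without E138A 2.

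**Figure D1:**
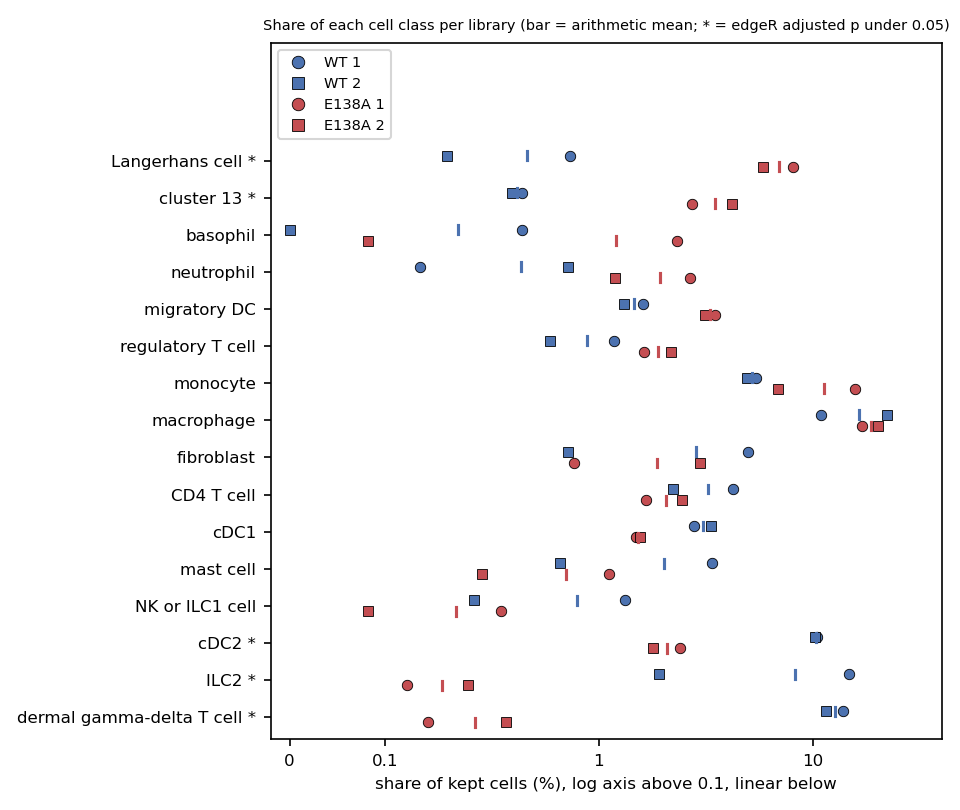
Share of kept cells (%) in each named class and in cluster 13, for WT 1, WT 2, E138A 1 and E138A 2, on an axis that is logarithmic above 0.1 and linear below; points are libraries, bars the mean of a genotype and stars an edgeR adjusted p under 0.05. Dermal gamma-delta T cells lie at 13.8% and 11.5% in WT against 0.159% and 0.367% in E138A, and Langerhans cells at 0.732% and 0.196% against 8.07% and 5.83%.

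Among T cells, 70.1% in WT 1 and 78.1% in WT 2 were gamma-delta cells, against 2.58% in E138A 1 and 4.0% in E138A 2. Cluster 13 made up 2.24% and 2.68% of T cells in WT and 44.3% and 45.8% in E138A. Regulatory T cells, which restrain other T cells, made up 5.97% and 4.02% against 26.3% and 23.6%, and CD4 T cells 21.6% and 15.2% against 26.8% and 26.7%. These shares of 134, 224, 194 and 225 T cells were not tested. A fall of the gamma-delta share raises the shares of the other T cell classes. Of all cells, CD4 T cells made up 4.25% and 2.23% in WT and 1.65% and 2.45% in E138A. Regulatory T cells made up 1.17% and 0.589% against 1.62% and 2.16%, and neither share of all cells passed. The share of T cells with a UMI of the IL-17 genes Il17a or Il17f (chromosome 1, 20730905 to 20734496 and 20777146 to 20790617) did not pass, while the cells that held these UMIs differed. In WT, 96.1% of the 1676 Il17a UMIs and 97.1% of the 308 Il17f UMIs lay in gamma-delta cells. In E138A, 89.4% of the 4964 Il17a UMIs, 90.9% of the 3446 Il17f UMIs and 87.0% of the 11069 UMIs of Il22, an epithelial repair cytokine, lay in cluster 13.

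With each cell thinned to 1500 UMIs, Il17a or Il17f was found in 27.6% and 20.5% of WT T cells and in 36.9% and 32.2% of E138A T cells (log2 fold 0.53, SE 0.46, edgeR adjusted p = 0.430; 0.48 and 0.441 without thinning). The share with Il22 (chromosome 10, 118204942 to 118210047) rose from 0 of 127 cells, which allows up to 2.86%, and 2.44% to 39.0% and 26.0% (log2 fold 4.48, SE 1.08, edgeR adjusted p = 0.0360). The Il22 share missed the threshold without thinning (log2 fold 4.15, adjusted p = 0.0648), and with thinning it missed it without E138A 1 (0.221) or E138A 2 (0.162). Without WT 2, which holds all WT cells with Il22, its log2 fold was 8.82, and without WT 1 it was 3.70. Il13, a type 2 cytokine, was in 0 of 127 and 0 of 205 thinned WT T cells, which allows up to 2.86% and 1.78%, and rose to 21.9% and 12.5% of E138A T cells (edgeR adjusted p = 0.00857; 0.00540 without thinning; thinned, 0.164 without E138A 1 and 0.125 without E138A 2). Il17f alone did not pass (12.6% and 8.78% against 28.9% and 19.2%, log2 fold 1.17, SE 0.54, edgeR adjusted p = 0.168), nor did Ifng (log2 fold -0.64, adjusted p = 0.556). Macrophages, which should lack these genes, gave a background of 0% and 0% in WT and 1.17% and 0.265% in E138A for Il17a or Il17f, of 0% and 0% against 0.703% and 0.794% for Il22, and of 0.234% in E138A 1 for Il13. Median UMIs per cell were 3556, 4144.5, 4383 and 4432 in T cells and 2631, 4275, 2772 and 2236 in macrophages.

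**Figure D2:**
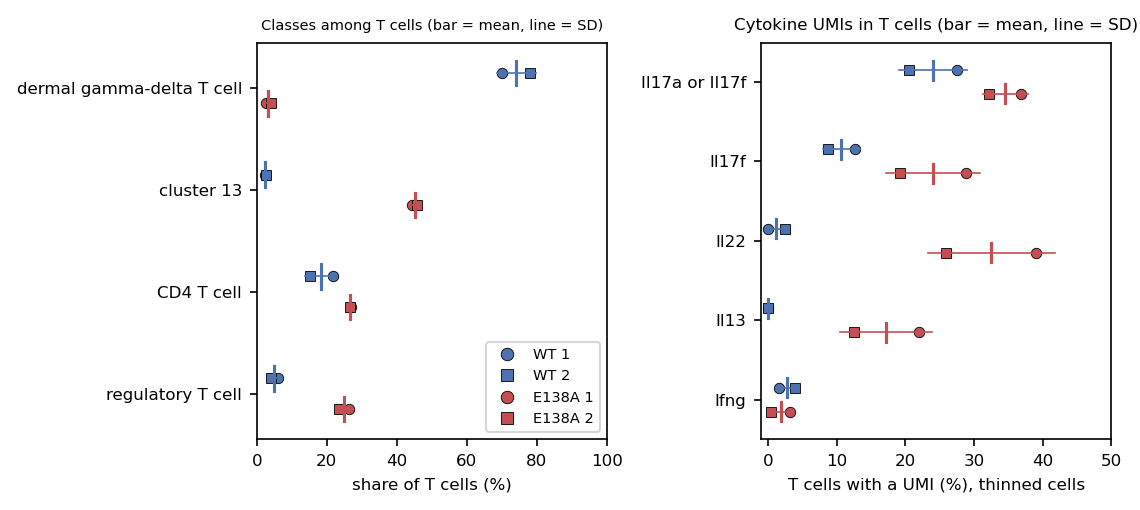
Left, share of T cells (%) in each T cell class; right, share of T cells (%) with a UMI of each cytokine after thinning to 1500 UMIs per cell; points are the libraries WT 1, WT 2, E138A 1 and E138A 2, bars the mean and lines the SD of a genotype. Cluster 13 lies at 2.24% and 2.68% in WT against 44.3% and 45.8% in E138A, and Il22 at 0% and 2.44% against 39.0% and 26.0%.

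Within CD4 T cells, Il22, Il17f and Gzmb were higher in E138A and Atf3 was lower. Il22 had 0 and 1 UMIs in WT and 150 and 180 in E138A, a ratio of 144 (95% interval 25.7 to 5705; adjusted p = 9.82e-05), and lay in 5 of 52 and 10 of 60 E138A cells. Its level was 656 and 647 CPM there against 10.2 and 5.71 CPM in macrophages of the same libraries. Il17f had a ratio of 29.7 (95% interval 5.15 to 1189; adjusted p = 0.0227), and Gzmb, a protease of killer cells, was at least 9.2-fold higher (adjusted p = 0.0169). Atf3, a stress-induced transcription factor, fell (log2 fold -3.02, SE 0.44, adjusted p = 0.0169). In all, 3 genes rose and 1 fell among 2715. Il17a (log2 fold 0.42, adjusted p = 0.947), Areg (2.11, 0.220), Ifng (-1.04, 0.791), the T cell factor Batf (2.57, 0.0626) and Cd40lg (-2.27, 0.0626) did not pass, nor did Il13 (ratio 64.1, 95% interval 11.3 to 2551, adjusted p = 0.471). Without E138A 1, 29 genes passed, and 25 without E138A 2. Il17f missed the threshold without WT 1 (adjusted p = 0.115) or E138A 2 (0.0555), Gzmb without WT 1 (0.0922), WT 2 (0.0505) or E138A 2 (0.137), and Atf3 without WT 2 (0.0567, log2 fold -2.40). The 1 WT UMI of Il22 and that of Il17f lie in WT 2. Gzmb, Il17f and Atf3, but not Il22, also missed it without the top doublet scores (0.0934, 0.0934 and 0.283), with stricter cells (0.0901 each) and with library totals (0.0909, 0.109 and 0.0763), and Gzmb at resolution 0.5 (0.101). At resolution 2 the class splits, and 6 of 29, 10 of 34, 29 of 52 and 6 of 60 of its cells (WT 1, WT 2, E138A 1, E138A 2) form a cluster led by Gzmc and Xcl1, while the 4 genes passed in the other 124 cells.

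Of the 17 lists tested in CD4 T cells, 6 were called at the preset correlation, and each gave adjusted p = 0.534 with an estimated correlation. The type 17 program was higher, with 2 of 14 members risen (3 adjusted over the list alone) and a camera adjusted p of 0.00446. The dissociation stress list was lower, with 1 of 17 fallen (7 adjusted over the list alone, adjusted p = 7.32e-07). Members of 4 called lists did not pass one by one over all genes in edgeR. These were the ribosomal proteins, higher (82 members, 17 at an unadjusted p under 0.05, 12 in DESeq2, 3 adjusted over the list alone, camera adjusted p = 1.61e-09), and the interferon response, lower (14 members, 3 unadjusted, 0 in DESeq2, 2 adjusted over the list alone, 0.000269). Oxidative phosphorylation was higher (26 members, 4 unadjusted, 0 in DESeq2 and 0 adjusted over the list alone, 0.0133), as were NF-kB and inflammatory cytokines (14 members, 1 unadjusted, 0 in DESeq2 and 0 adjusted over the list alone, 0.0266).

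Over all T cells summed, a comparison added after the classes were seen, 311 genes rose and 198 fell among 8013, and the sums mix the classes above. Il13 had a ratio of 175 (95% interval 59.6 to 850; adjusted p = 3.45e-05), and Tff1, a secreted trefoil peptide, was at least 146.3-fold higher (adjusted p = 1.33e-05). Trdc, the constant region of the delta chain (chromosome 14, 54142851 to 54148868), fell by 3.47 on the log2 scale (SE 0.27, adjusted p = 3.45e-05), and Sox13, a factor of gamma-delta T cells, fell by 4.13 (SE 0.42, adjusted p = 0.000165). Il17f rose by 2.95 (SE 0.45, adjusted p = 0.00778). It missed the threshold without WT 1 (0.427) or WT 2 (0.596), where its log2 fold was 3.02 and 2.90, and that fold was 2.102 without E138A 1. Areg, an epithelial growth factor, rose by 1.35 (SE 0.31, adjusted p = 0.0216), and missed the threshold without WT 1 (0.165, log2 fold 1.19), WT 2 (0.0955, 1.55) or E138A 2 (0.211, 0.85). Il13, with 2 UMIs in WT 1 and 1 in WT 2, had a log2 fold of 8.42 without WT 1 and 6.48 without WT 2. It missed the threshold with centred components (0.0737) and at resolution 0.5 (0.629, log2 fold 1.35), and Areg at resolution 0.5 (0.124). Il17a (log2 fold 1.13, adjusted p = 0.284) and Il22 (8.22, adjusted p = 0.140) did not pass.

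The regulatory T program was higher in the sum of T cells, with 7 of 11 members risen (10 adjusted over the list alone, camera adjusted p = 8.64e-08; adjusted p = 0.578 with an estimated correlation). Its master regulator Foxp3 rose by 2.28 (SE 0.39, edgeR adjusted p = 0.00438), with a log2 fold of 2.88 without WT 1 and 1.64 without WT 2. Ctla4, a brake on T cell help, rose by 1.78 (SE 0.23, edgeR adjusted p = 0.000781). These sums follow the mix of T cell classes. Regulatory T cells made up 5.97% and 4.02% of T cells in WT and 26.3% and 23.6% in E138A. Gamma-delta cells made up 70.1% and 78.1% against 2.58% and 4.0%. Changes of genes within regulatory T cells were not tested. The dissociation stress list was lower, with 11 of 20 fallen (13 fallen and 1 risen adjusted over the list alone, camera adjusted p = 1.08e-07; adjusted p = 0.776 with an estimated correlation), among them Atf3 (log2 fold -3.17, SE 0.27, adjusted p = 5.82e-05) and Egr1 (-2.09, SE 0.23, adjusted p = 0.000335). Antigen presentation (2 of 16 risen, 2 adjusted over the list alone, camera adjusted p = 0.0140), resident macrophage genes (3 of 8 risen, 3 risen and 1 fallen adjusted over the list alone, 0.0159) and oxidative phosphorylation (3 of 26 risen, 3 adjusted over the list alone, 0.0118) were higher. These 3 lists also gave adjusted p = 0.776 with an estimated correlation. Macrophage marker RNA in these T cells was also higher, at 90.2 and 81.5 CPM in WT and 773 and 443 CPM in E138A. The type 17 program was not called (4 of 24 risen and 4 fallen, 5 and 7 adjusted over the list alone, adjusted p = 0.630), with a negative median and a positive mean log2 fold.

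In the sum of all cells, Mfge8, a Langerhans marker in the fixed sets, rose from 75.1 and 65.9 CPM to 1876 and 1560 CPM (log2 fold 4.61, SE 0.18, adjusted p = 0.00745). Pgf, a placental growth factor of the VEGF family, rose by 4.01 (SE 0.20, adjusted p = 0.00798), Spint1, a protease inhibitor of epithelia, by 3.65 (SE 0.18, adjusted p = 0.00798), and Uchl1, a deubiquitinase, by 5.81 (SE 0.40, adjusted p = 0.0203). Trdc fell by 3.83 on the log2 scale (SE 0.21, adjusted p = 0.0115). Igha, the constant region of IgA, was at least 87.7-fold higher (adjusted p = 0.0206), and missed the threshold without E138A 1 (0.0695). In all, 32 genes rose and 21 fell among 12630, and 206 passed without WT 1, 155 without WT 2 and 9 without E138A 1. With a term for replicate number, which also follows the sex-linked genes, 0 genes passed in edgeR, with 1638 at an unadjusted p under 0.05. All 22 named calls in the sum of all cells then missed the threshold, and the closing section gives the limits of that term. Without the top doublet scores 12 passed, 10 higher and 2 lower, and Icam1, Tnf, Ffar2, Sox13, Klrk1 and Cd163l1 of this and the next paragraph missed the threshold (0.0569 each, and 0.0601 for Cd163l1), as did Tnf with library totals (0.0532). Icam1, an adhesion molecule induced by NF-kB, fell by 1.90 (SE 0.17, adjusted p = 0.0396), and missed the threshold without E138A 1 (0.119, log2 fold -2.05) or E138A 2 (0.0784, -1.77). Tnf, an inflammatory cytokine, fell by 1.72 (SE 0.20, adjusted p = 0.0490), and missed it without WT 2 (0.0532, log2 fold -1.61), E138A 1 (0.137, -1.97) or E138A 2 (0.107, -1.52). Il22 was at 0 and 2.59 CPM in WT and 532 and 224 CPM in E138A and did not pass (adjusted p = 0.0805), nor did Il17f (log2 fold 2.25, 0.0786), Il17a (0.50, 0.408), Il1b (0.95, 0.0907), Il23a (1.75, 0.280), Il23r (-1.26, 0.191), S100a8 (1.28, 0.513) or S100a9 (1.00, 0.616).

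Of the 26 lists tested in the sum of all cells, 7 were called, 3 higher and 4 lower. The metabolite receptor and amino acid transport list was higher, with 1 of 22 members risen (8 risen and 1 fallen adjusted over the list alone, camera adjusted p = 0.00249; adjusted p = 0.871 with an estimated correlation). That member is Ffar2, a receptor for short-chain fatty acids (log2 fold 4.38, SE 0.43, adjusted p = 0.0455), which missed the threshold without WT 2 (0.0741) or E138A 1 (0.139). The cystine transporter Slc7a11 (1.17, 0.0989) and the vitamin D receptor Vdr (1.78, 0.101) did not pass. The type 17 program was lower, with 2 of 24 fallen (2 risen and 8 fallen adjusted over the list alone, camera adjusted p = 0.0165, and 0.871 with an estimated correlation). The fallen members are Sox13 (log2 fold -3.87, SE 0.38, edgeR adjusted p = 0.0455) and Cd163l1, a gamma-delta scavenger receptor (-3.53, SE 0.35, 0.0490). Both are in the marker set of dermal gamma-delta T cells, which fell from 13.8% and 11.5% of cells in WT to 0.159% and 0.367% in E138A. The sum mixes this loss with changes within cells, and Il17a, Il17f and Il22 of the list did not fall. Sox13 and Cd163l1 both missed the threshold without E138A 1 (0.181) and without E138A 2 (0.0878 and 0.0561). The type 1 program was lower, with 1 of 15 fallen (4 adjusted over the list alone, 0.000735; adjusted p = 0.871 with an estimated correlation). That was Klrk1, a killer cell receptor (-1.62, SE 0.16, adjusted p = 0.0455), which missed the threshold without E138A 1 (0.209) or E138A 2 (0.1002).

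Members of the other 4 called lists did not pass one by one over all genes in edgeR. Oxidative phosphorylation was higher (26 members, 16 at an unadjusted p under 0.05, 7 in DESeq2, 9 adjusted over the list alone, camera adjusted p = 5.43e-05), and Atp5e, an ATP synthase subunit, had a log2 fold of 0.83 (adjusted p = 0.0805). Cholesterol and lipid synthesis was higher (21 members, 10 unadjusted, 1 in DESeq2, 8 adjusted over the list alone, 0.00249), and its enzyme Idi1 had a log2 fold of 1.10 (adjusted p = 0.0710). Dissociation stress was lower (21 members, 9 unadjusted, 4 in DESeq2, 2 adjusted over the list alone, 0.00197). The interferon response was lower (46 members, 4 lower and 1 higher unadjusted, 2 lower in DESeq2, 0 adjusted over the list alone, 0.0414). That list gave adjusted p = 0.905 with an estimated correlation, and each of the other 6 gave adjusted p = 0.871 with an estimated correlation. With that correlation 0 lists passed, also at an unadjusted p under 0.05, and fry called 0, with 3 unadjusted.

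Within macrophages, Il1b and Ccl8 were among the genes higher in E138A and Cd36 and Slc40a1 among those lower. The inflammatory cytokine Il1b rose by 1.80 on the log2 scale (SE 0.21, adjusted p = 2.09e-05), and the chemokine Ccl8 (chromosome 11, 82115185 to 82116799) rose from 3092 and 3218 CPM to 9986 and 10530 CPM (log2 fold 1.70, SE 0.18, adjusted p = 1.02e-05). Cd36, a lipid scavenger receptor, fell by 2.52 (SE 0.21, adjusted p = 4.71e-07), and the iron exporter Slc40a1 by 2.94 (SE 0.49, adjusted p = 0.00114; 0.0846 at resolution 2). Nrg1, a growth factor, was at least 39.3-fold higher (adjusted p = 8.65e-07), and Pgf had a ratio of 42.7 (95% interval 14.4 to 209; adjusted p = 5.12e-05), with 2 UMIs in WT 1 and 1 in WT 2 and a log2 fold of 6.65 without WT 1 and 2.97 without WT 2. In all, 177 genes rose and 103 fell among 8549, and 531 passed without WT 1 and 127 without E138A 1. The class joins clusters 0 and 6, and cluster 6 gave 42 and 202 of its WT cells but 57 and 87 of its E138A cells, against 32, 135, 478 and 408 for cluster 0. Cd36 is among the 30 leading genes of cluster 6, so its fall may follow this mix in part. Clusters 0 and 6 were also fitted apart, and 78 genes rose and 55 fell in cluster 0 and 56 and 57 in cluster 6. Of those folds only that of Ccl8 is given below. For the other genes, the mix and a change within a cluster are not told apart gene by gene here.

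Of the integrin and chemokine receptors, 4 of 13 rose and 1 fell in macrophages (6 and 2 adjusted over the list alone), including Ccr1 (2.02, SE 0.30, adjusted p = 0.000468) and Ccr2 (1.53, SE 0.27, adjusted p = 0.00312; 2.15 without WT 2), receptors that guide monocytes into tissue. This list was not called (adjusted p = 0.0616). Neutrophil activation was higher, with 4 of 10 risen (4 adjusted over the list alone, camera adjusted p = 0.00545; adjusted p = 0.690 with an estimated correlation), among them S100a8 (3.73, SE 0.54, adjusted p = 0.000311; 0.115 without WT 2, log2 fold 2.76) and the IL-1 decoy receptor Il1r2 (3.04, SE 0.46, adjusted p = 0.000584; 0.0862 without WT 2, log2 fold 2.23). In E138A, neutrophils held 79.6% of S100a8 UMIs, while 97 lay in macrophages, in 68 of 1030 cells, and neutrophils made up 0.146% and 0.720% of cells in WT and 2.67% and 1.18% in E138A. Resident macrophage genes were lower, with 3 of 19 fallen and 1 risen (7 and 2 adjusted over the list alone, 0.00545). Both lists and dissociation stress (4 of 21 fallen, 8 adjusted over the list alone, 0.00288) gave a camera adjusted p of 0.690 with an estimated correlation. The fall of resident macrophage genes may follow the mix of clusters 0 and 6 in part. Lists were not tested in either cluster alone. Cholesterol synthesis (2 of 19 risen, 5 adjusted over the list alone, 0.00545) and metabolite receptors (3 of 15 risen and 1 fallen, 6 and 1 adjusted over the list alone, 0.00828) were higher and gave adjusted p = 0.773 with an estimated correlation. The fallen member is Gpr84, a fatty acid receptor (-3.02, SE 0.60, adjusted p = 0.00453). The interferon list was called higher (0.00828), although 1 of its 33 members fell and the others did not pass over all genes (7 higher at an unadjusted p under 0.05 in edgeR, 0 in DESeq2, 1 fallen adjusted over the list alone), and it gave adjusted p = 0.875 with an estimated correlation. Tnf fell by 1.01 (SE 0.25, adjusted p = 0.0211), and missed the threshold without E138A 2 (0.284, log2 fold -0.72), in DESeq2 (0.0974) or thinned to equal depth (0.146), and Cxcl2 (-0.48, 0.168) and Il6 (0.43, 0.616) did not pass.

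Within monocytes, Pgf, Nrg1 and Sdc4 were among the genes higher in E138A and Cd177 was lower. Pgf had a ratio of 62.3 (95% interval 11.1 to 2468; adjusted p = 0.00784; its 1 WT UMI lies in WT 2), and Nrg1 rose by 3.14 (SE 0.38, adjusted p = 0.0159; 4.40 without WT 2). The proteoglycan Sdc4 rose by 1.99 (SE 0.21, adjusted p = 0.00784), and the mannose receptor Mrc1 by 1.77 (SE 0.27, adjusted p = 0.0396; 2.46 without WT 2). Cd177, a surface protein of neutrophils, fell by 1.97 (SE 0.29, adjusted p = 0.0391). Lyz1 fell by 2.15 (SE 0.31, adjusted p = 0.0391), a value left uncertain because its reads can be shared with the near-identical Lyz2. In all, 9 genes rose and 2 fell among 6207, and 72 passed without WT 1, 25 without WT 2, 50 without E138A 1 and 61 without E138A 2. Osm, a cytokine of the IL-6 family, rose by 1.33 (SE 0.20, adjusted p = 0.0396), and missed the threshold without WT 2 (0.0510, log2 fold 1.39). Mrc1 missed the threshold with library totals (0.0502), at resolution 0.5 (0.0631) and at resolution 2 (0.0956), Cd177 at resolution 2 (0.0956) and thinned (0.176), and Lyz1 with centred components (0.604) and at resolution 2 (0.602). Il1b (0.58, 0.453), Tnf (-1.60, 0.0625), Cxcl2 (0.03, 0.995) and Il6 (0.06, 0.996) did not pass.

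Of the 19 lists tested in monocytes, 4 were called, and each gave adjusted p = 0.762 with an estimated correlation. Resident macrophage genes were higher, with 1 of 15 risen (6 adjusted over the list alone, camera adjusted p = 0.00369). The interferon response was lower, although its 37 members did not pass one by one in edgeR (10 lower at an unadjusted p under 0.05, 2 in DESeq2, 3 adjusted over the list alone, 1.74e-05); its member Ifitm3 had a log2 fold of -0.98 (adjusted p = 0.134). Mitochondrially encoded genes (13 members, 0 past the edgeR threshold, 4 unadjusted, 3 in DESeq2, 3 adjusted over the list alone, 0.000647) and ribosomal proteins (89 members, 0 past the edgeR threshold, 15 unadjusted, 11 in DESeq2, 10 adjusted over the list alone, 0.00476) were higher.

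Within cDC2, Icam1, Tnf and Cd74 were among the genes lower in E138A and Ifitm1 and Cdh1 among those higher. Icam1 fell by 3.69 (SE 0.28, adjusted p = 4.26e-07; -4.60 without E138A 1), Tnf by 2.46 (SE 0.38, adjusted p = 0.000713) and the NF-kB inhibitor Nfkbia by 1.27 (SE 0.17, adjusted p = 0.000171). Cd74, the invariant chain of MHC class II, fell by 1.27 (SE 0.18, adjusted p = 0.000301), and the class II gene H2-Aa by 1.00 (SE 0.16, adjusted p = 0.000975). Higher genes included Ifitm1 (3.34, SE 0.26, adjusted p = 4.96e-07), the adhesion gene Cdh1 (3.81, SE 0.39, adjusted p = 7.72e-06) and the homing receptor Ccr9 (3.22, SE 0.50, adjusted p = 0.000713; 3.89 without WT 1 and 2.14 without WT 2). Ccl8 had a ratio of 64.0 (95% interval 21.2 to 316; adjusted p = 1.83e-06), at 0 and 2.35 CPM in WT and 103 and 104 CPM in E138A (its 3 WT UMIs lie in WT 2), levels far below those of macrophages. In all, 92 genes rose and 171 fell among 5117, against 155 and 111 with library totals, and 165 passed without WT 2. Il1b did not pass (-0.30, 0.554).

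The list of NF-kB and inflammatory cytokines was lower in cDC2, with 8 of 21 fallen and 2 risen (10 and 2 adjusted over the list alone, camera adjusted p = 0.00225; adjusted p = 0.529 with an estimated correlation). The risen members are Ptgs2, which makes prostaglandins (3.09, SE 0.55, adjusted p = 0.00275), and Osm (2.49, SE 0.54, adjusted p = 0.00937), which missed the threshold without E138A 1 (0.397 and 0.758, log2 folds 2.68 and 1.87; Osm also without WT 2, 0.0994). The 11 WT UMIs of Ptgs2 lie in WT 2. Antigen presentation was lower, with 6 of 23 fallen and 1 risen (10 and 1 adjusted over the list alone, 0.0182), as were resident macrophage genes (5 of 9 fallen, 5 fallen and 1 risen adjusted over the list alone, 0.0112) and dissociation stress (9 of 20 fallen, 13 adjusted over the list alone, 4.72e-06), each with adjusted p = 0.529 with an estimated correlation. Oxidative phosphorylation (1 of 26 risen, 2 adjusted over the list alone, 0.00438) and mitochondrially encoded genes (1 of 13 risen, 1 adjusted over the list alone, 0.0423) were higher. These 2 lists also gave adjusted p = 0.529 with an estimated correlation.

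**Figure D3:**
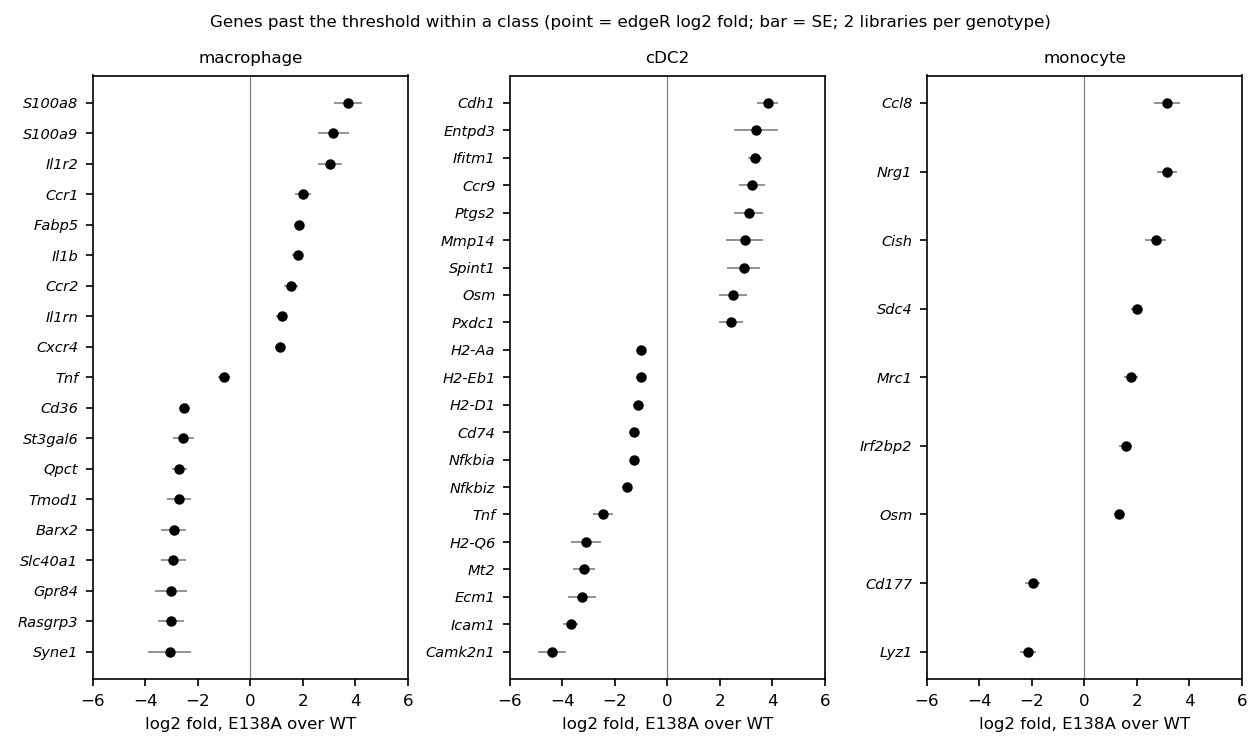
Log2 fold, E138A over WT, of a selection of genes past the threshold within macrophages, cDC2 and monocytes; points are edgeR folds and bars their SE over 2 libraries per genotype. Il1b lies at 1.80 and Cd36 at -2.52 in macrophages, Icam1 at -3.69 in cDC2 and Nrg1 at 3.14 in monocytes.

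Cluster 3, myeloid cells led by Ear2, Sirpb1c and Clec4b1, had 73 genes higher and 28 lower in E138A among 5674, and 61 passed without E138A 1. At resolution 2, in the matching cluster of 485 cells, 0 of 4428 genes passed in edgeR, with 449 at an unadjusted p under 0.05 (DESeq2 was not run there), and the 10 named calls that could be tested missed the threshold, among them Clec4n (0.0745), Ccnd1 (0.162), Lyz1 (0.588), Ccl8 (0.1096) and Osm (0.1096). The C-type lectin Clec4n rose by 2.63 (SE 0.31, adjusted p = 1.11e-05; 2.00 without WT 2). The cell cycle gene Ccnd1 fell by 2.19 (SE 0.29, adjusted p = 3.62e-05), Lmo1, a transcription cofactor, by 1.92 (SE 0.27, adjusted p = 5.72e-05) and the ganglioside enzyme St3gal5 by 3.75 (SE 0.55, adjusted p = 0.000116). Lyz1 fell by 2.30 (SE 0.22, adjusted p = 1.87e-07), uncertain as in monocytes. Ffar2 was at least 4.7-fold higher (adjusted p = 0.0114), and missed the threshold without WT 2 (0.1496) or E138A 2 (0.117). Il1b did not pass (2.53, 0.1205). Mitochondrially encoded genes (3 of 13 risen, 3 adjusted over the list alone, camera adjusted p = 0.0139), oxidative phosphorylation (1 of 26 risen, 6 adjusted over the list alone, 0.0139) and neutrophil activation (7 members, 0 past the edgeR threshold, 4 unadjusted, 0 in DESeq2, 4 adjusted over the list alone, 0.0139) were higher. For each of these 3 lists, adjusted p = 0.814 with an estimated correlation.

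Cluster 4, myeloid cells led by Lyz1, Tnip3 and Cd209a, had 6 genes higher and 2 lower in E138A among 4083. The matrix protein Thbs1 rose by 3.33 (SE 0.36, adjusted p = 0.000118). Icam1 fell by 1.55 (SE 0.23, adjusted p = 0.00385). The phosphatase gene Dusp2 fell by 2.01 (SE 0.35, adjusted p = 0.0221; -2.70 without E138A 2), and missed the threshold without E138A 1 (0.0542, log2 fold -1.52) or thinned (0.0677). Thbs1 did not pass with centred components (0.968, log2 fold 0.39). Tnf did not pass (-1.82, 0.0535). The count was 59 without WT 1, 41 without WT 2, 24 without E138A 1 and 213 without E138A 2. Members of the 4 called lists did not pass one by one in edgeR, and each list gave adjusted p = 0.686 with an estimated correlation. Resident macrophage genes (13 members, 7 higher and 1 lower at an unadjusted p under 0.05, 1 in DESeq2, 6 adjusted over the list alone, camera adjusted p = 0.00868) and lipid uptake (10 members, 4 unadjusted, 1 in DESeq2, 2 adjusted over the list alone, 0.0336) were higher. Antigen presentation (21 members, 6 unadjusted, 3 in DESeq2, 0 adjusted over the list alone, 0.0419) and ribosomal proteins (86 members, 27 lower and 5 higher unadjusted, 5 lower and 3 higher in DESeq2, 0 adjusted over the list alone, 0.000832) were lower.

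Across the 5 myeloid classes tested, Ccl8 and Osm were each past the threshold and higher in 5, which is macrophages, monocytes, cDC2 and clusters 3 and 4. In cluster 3, Ccl8 rose by 4.37 (SE 0.46, adjusted p = 0.000280; 0.334 without WT 1, and log2 fold 3.75 without E138A 2), and in cluster 4 by 4.51 (SE 0.39, adjusted p = 1.32e-05; 6.08 without WT 2). In monocytes Ccl8 rose by 3.14 (SE 0.50, adjusted p = 0.0475; log2 fold 2.47 without E138A 1; p-values of 0.114 without WT 1, 0.254 without WT 2, 0.0502 with library totals, 0.0504 with stricter cells and 0.0734 at resolution 0.5). Osm in cluster 4 rose by 2.03 (SE 0.38, adjusted p = 0.0331; 0.408 without E138A 1 and 0.234 thinned), and in cluster 3 it had a ratio of 13.1 (95% interval 3.52 to 110; adjusted p = 0.00192; its 2 WT UMIs lie in WT 2). Cish, an inhibitor of cytokine signalling, was higher in 4 of these classes and lost that call in monocytes without WT 2 (0.157) and in cluster 4 without WT 2 (0.115) or E138A 1 (0.0965) or thinned (0.155). Icam1 was lower in 3 of them. Whether these effects differ between classes was not tested.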

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

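No test here was chosen after the result was seen, and no explanation was weighed for these values. The share of fibroblasts, an outlying class in a CD45+ sort, moved in opposite directions in the same-numbered libraries. E138A over WT it was 0.153-fold for the libraries numbered 1 and 4.14-fold for those numbered 2, each beyond its counting intervals, and the difference was not tested. The labels do not say that equal numbers pair the samples.

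Sex-linked genes stood outside the comparisons and gave a signal above the floor of 3 UMIs. Xist, expressed from the inactive X chromosome, had 1356 UMIs in WT 1 and 3886 in E138A 1 and 0 in the other libraries. The Y-linked gene Ddx3y had 623 UMIs in WT 2 and 660 in E138A 2 and 0 in the other libraries.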

How the results depend on the processing

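The sum of all T cells, the crossed pairing, the separate macrophage clusters, the fit of the all-cell sum without the top doublet scores, the separate tests of Il17f, Il22, Il13 and Ifng and the adjustment over cytokine sets were chosen after seeing the data; the other alternatives were planned. Of 161 calls on named genes, 58 passed in the same direction in every setting that tested them, 88 did so in every setting that left no library out, and 0 changed direction in any setting. Per setting, 0 of 161 calls missed the threshold with DESeq2 size factors, 6 of 103 with DESeq2, 17 of 161 with library totals, 35 of 161 with a term for replicate number, 44 of 155 without E138A 1, 27 of 160 without E138A 2, 19 of 161 without WT 1 and 51 of 149 without WT 2. Class share calls numbered 6 to 10 in the settings that kept all libraries. For each value below the cause was not tested, except where the paragraph on cytokine shares gives it.

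The number of genes past the threshold moved by over 1.5 times in these settings. In the sum of all cells it went from 53 to 499 with DESeq2, 33 with library totals, 351 with no filter on low counts and 12 without the top doublet scores. In CD4 T cells it went from 4 to 7 with a filter of 10 counts, 23 with DESeq2, 1 with library totals, 39 with no filter, 1 without the top doublet scores, 129 at resolution 0.5, where the class of that name holds 593 cells led by Il22, Il17f and Il17a in place of 175, 26 at resolution 2, 1 with stricter cells and 31 thinned to equal depth. In macrophages it went from 280 to 161 with DESeq2, 166 thinned, 133 in cluster 0 alone and 113 in cluster 6 alone. In monocytes it went from 11 to 36 with a filter of 10 counts, 53 with DESeq2, 180 with no filter, 25 without the top doublet scores, 7 at resolution 2 and 51 thinned. In cDC2 it went from 263 to 93 with DESeq2 and 163 thinned. In cluster 3 it went from 101 to 183 with no filter and, in edgeR, to 0 at resolution 2, where 449 of 4428 genes had an unadjusted p under 0.05; DESeq2 was not run at that resolution. In cluster 4 it went from 8 to 44 with a filter of 10 counts, 33 with DESeq2 size factors, 45 with DESeq2, 105 with centred components, 21 with library totals, 92 with no filter, 25 without the top doublet scores, 74 at resolution 0.5, 52 at resolution 2, 34 with stricter cells and 5 thinned. Over all T cells it went from 509 to 241 with DESeq2 and 883 with no filter. The calls on gene lists, counted without the 5 in the added sum of all T cells, went from 36 to 0 with camera's estimated correlation and to 1 with fry, in monocytes, where the lowest fry adjusted p was 0.0229.

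With a term for replicate number, which pairs same-numbered samples as a block, the count was 0 in the sum of all cells in edgeR (1638 genes at an unadjusted p under 0.05, and 499 by DESeq2 without the term), 26 in CD4 T cells, 428 in macrophages, 5 in monocytes, 452 in cDC2, 158 in cluster 3 and 2 in cluster 4. With it, 22 of 22 named calls missed the threshold in the sum of all cells, 6 of 10 in monocytes and 6 of 8 in cluster 4. The term follows the sex-linked genes too, since both libraries numbered 1 carry Xist UMIs and both numbered 2 Ddx3y UMIs. The labels do not say that the numbers pair the samples, and in the sum of all cells the fold residuals of same-numbered libraries had a correlation of -0.25. With the opposite pairing the count was 16 in CD4 T cells, 181 in macrophages, 41 in monocytes and 72 in cluster 4.

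Leaving out 1 library leaves 1 sample in a genotype, which is assumed to vary like the others in a fit that pools the spread. The count then ranged from 9 to 206 in the sum of all cells, 4 to 29 in CD4 T cells, 127 to 531 in macrophages, 25 to 72 in monocytes, 165 to 355 in cDC2, 61 to 145 in cluster 3, 24 to 213 in cluster 4 and 349 to 608 over all T cells. The number of class shares past the threshold ranged from 0 to 7 (6 at an unadjusted p under 0.05 in edgeR where it was 0, without E138A 1), and that of gene lists from 30 to 52.

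Values that changed direction were those of shares that had not passed, and they are given with other values of these shares with a library left out. The log2 fold of the macrophage share was -0.35 with TMM over classes, -0.026 at resolution 0.5, -0.25 without WT 1 and 0.78 without WT 2, and that of the CD4 T cell share 0.85 at resolution 0.5, in the larger class named above. Without WT 1 it was 1.36 for fibroblasts, 0.11 for mast cells, -1.05 for cluster 9, -0.46 for cluster 16 and 7.86 for basophils. Without WT 2 it was 0.031 for cluster 9 and 0.34 for cluster 16. Without E138A 1 it was 0.11 for fibroblasts, 0.08 for cluster 16, -0.95 for basophils and -2.73 for mast cells, and without E138A 2 it was -1.85 for fibroblasts. The Ifng share of T cells was at 0.19 without WT 2, 0.17 without E138A 2 and -2.41 without E138A 1.

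The adjustment over cytokine sets, chosen after the unadjusted p-values had been seen, changed calls on Il22 and Il13. Unadjusted edgeR values for the Il22 share were 0.0103 thinned and 0.0185 not thinned, where the adjusted p was 0.0360 and 0.0648, so the call without thinning ends by the adjustment alone. Thinned and without E138A 2, the unadjusted value was 0.0463 for Il22. For the Il13 share it was 0.0234 without E138A 1 and 0.0179 without E138A 2, so these calls too end by the adjustment. Without E138A 1 the Il22 share missed the threshold either way (0.0630 unadjusted), as did Il17a or Il17f with all libraries (0.307), Il17f (0.0774) and Ifng (0.556).

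Library totals in place of TMM shifted the median log2 fold of all genes by -0.15 in CD4 T cells and by 0.19 in cDC2, where higher genes made up 58.3% of the calls against 35.0%. Depth limits which genes can be tested, 2715 in CD4 T cells against 12630 in the sum of all cells. On simulated data, 9.70% of 2-fold changes were recovered in CD4 T cells and 23.7% in the sum of all cells.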

Other observations

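The test of doublets in cluster 13 and the tests of Ccl8 were set before their results were seen; the tests of the gamma-delta class and those of Cd4, Trdc, the innate-like genes and the share without top doublet scores in cluster 13 were chosen after. Some genes higher in E138A came mostly from cell types that are scarce in WT. Of 549 Igha UMIs in E138A, 502 (91.4%) lay in Langerhans cells, in 218 of 397 cells, and WT had 0 UMIs. The 436 Ffar2 UMIs of E138A were spread, with 28.9% in cluster 1, 24.8% in Langerhans cells and 12.6% in monocytes, against 10 UMIs in all WT cells. Il13 came from different cells in each genotype. In WT, ILC2 held 80.3% of its 269 UMIs, and in E138A cluster 13 held 64.6% of 985. Within cluster 13, Il22 and Il13 UMIs, not thinned, were found together in 58.1% of cells in E138A 1 (95% interval 47.0 to 68.7), against 56.3% for independent draws, and in 21.4% in E138A 2 (95% interval 13.9 to 30.5), against 16.4%. The growth factor gene Areg had 42.6% of its WT UMIs in gamma-delta cells and 54.0% of its E138A UMIs in cluster 13.

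The loss of dermal gamma-delta T cells could be a dilution by the classes that grew, a regrouping of the same cells or a lower yield. Dilution would keep their number per CD4 T cell if CD4 T cells had not entered with the classes that grew. That number was at most 0.15 in E138A against 3.24 and 5.15 in WT, so gamma-delta cells fell relative to CD4 T cells. The data hold no number of cells per ear, so dilution stays open where CD4 T cells entered too. Regrouping would keep the share of T cells with a Trdc UMI, but at equal depth it was at most 4.33% in E138A against 27.6% and 42.0% in WT. A lower yield of lymphocytes held in the tissue stays open, since the ILC2 share fell by a like amount in the full fit (log2 fold -5.43). It missed the threshold without E138A 1 or E138A 2. In the libraries numbered 1, the WT over E138A ratio of the share was 115 for ILC2 and 86.6 for gamma-delta cells. In those numbered 2 it was 7.75 and 31.2, so the likeness rests on WT 1. A loss of these cells in E138A skin is the biological explanation left beside these and was not tested beyond this.

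Cluster 13 may hold conventional CD4, gamma-delta or innate-like T cells. Conventional CD4 T cells are argued against by Cd4 UMIs, not thinned, in at most 7.77% of its E138A cells. The CD4 class of E138A had Cd4 UMIs in 23.1% and 46.7%. Gamma-delta cells are argued against as the bulk of its E138A cells by Trdc UMIs in at most 3.49% at equal depth (95% interval up to 9.86). WT gamma-delta cells had Trdc UMIs in 36.7% and 51.9%. Trac UMIs, not thinned, go the same way, in 55 of 86 and 53 of 103 E138A cells, against 14.9% and 16.6% of WT gamma-delta cells. Of the few WT cells of cluster 13, 3 of 3 in WT 1 and 2 of 6 in WT 2 had Trdc UMIs, not thinned. Some gamma-delta cells in cluster 13 of E138A are not excluded, since Tcrg-V4 UMIs, not thinned, were in 26.7% and 22.3% of its E138A cells. They were in 19 of 94 and 28 of 175 WT gamma-delta cells and 0 of 52 and 0 of 60 CD4 T cells of E138A. Innate-like alpha-beta T cells stay open. Zbtb16 and Blk UMIs were in 29.1% and 75.6% of cluster 13 cells in E138A 1 and 28.2% and 68.9% in E138A 2, against at most 1.67% of CD4 T cells, but WT gamma-delta cells carry both. Trav1 UMIs were in 12.8% of cluster 13 cells in E138A 1 and 18.4% in E138A 2, against 0 of 52 and 1 of 60 CD4 T cells. WT gamma-delta cells carried Trav1 UMIs too, in 8 of 94 and 8 of 175 cells. The intervals of cluster 13 and CD4 T cells overlapped in E138A 1 (6.56 to 21.7 against up to 6.85) and lay apart in E138A 2 (11.5 to 27.3 against 0.042 to 8.94). An overlap of intervals is not a test, so it does not show these shares to be alike. Doublets with top scores, 8.14% of its cells in E138A 1 (95% interval 3.34 to 16.1) and 6.80% in E138A 2, are argued against as the whole cause of its higher share, whose log2 fold was 2.94 without them (SE 0.60, adjusted p = 0.0166) while that of neutrophils went from 1.99 to 3.65, but doublets with lower scores stay open.

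Ccl8 was higher in the 5 myeloid classes tested, and free RNA from macrophages could account for it outside macrophages. In T cells the ratio of Ccl8 to macrophage marker UMIs was 0.658 of that in macrophages in E138A 1 and 0.803 in E138A 2, within the 2-fold range that a single source of free RNA would give; this ratio was not tested in the other myeloid classes. Other values go against such a source, and it stays open. Per 100 marker UMIs, CD4 T cells of E138A 2 had 114 Ccl8 UMIs (95% interval 80.4 to 162) against 50.7 in macrophages. Ccl8 UMIs were in 46 of 194 T cells but 4 of 73 basophils of E138A 1. Mast cells of E138A 1 had 2.17 per 100 (95% interval 0.59 to 5.66) against 48.4 in macrophages, which cannot decide it. Their marker level was high in WT too, at 3515 and 5490 CPM against 90.2 and 81.5 CPM in T cells, so the markers may be their own. Within macrophages, free RNA is argued against by a Ccl8 level at least 6.55 times that of all cells in E138A, and a different mix of the 2 macrophage clusters by a rise of at least 1.73 on the log2 scale in cluster 0 and in cluster 6 alone. A rise in macrophages of E138A remains a hypothesis.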
